A study of Mus musculus with 9 samples.

How the data were processed

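Libraries were made from poly(A) RNA with a directional kit and sequenced as read pairs, per the labels' protocols. STAR 2.7.9, featureCounts, limma and the mm39 build are named in the submitters' processing notes, with no roles or order, and the annotation release and the strand setting used in counting are not given in the sources used here. The deposited count table holds whole-number counts for 55359 genes in 9 libraries, and was used as deposited. A second table by the authors holds log2 CPM of 18833 genes, which matched log2((count + 0.5) / (total + 1) × 1e+06), with totals over the genes it lists, to within 5e-14, so that no scaling factor beyond the library total entered it. Gene identifiers were matched to symbols through a table of an older mouse annotation, GENCODE M21 on GRCm38, in which 52083 of the 55359 had a name. The files give no coordinates and none are printed, since that build differs from the one the submitters name. No column was left without a sample, and no entry of the count table lacked a gene.

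Samples were grouped by the treatment in their labels, 3 libraries each for PBS, IP and IV. The labels give each library a mouse number, with gaps (IP 2 to 4, IV 1, 2 and 4), and do not say that equal numbers in different groups are related. Counts were analysed with edgeR 4.0.16 in R 4.3.3: filterByExpr on the groups left 17123 genes, of which 17087 had a symbol, library sizes were scaled by TMM, and all 9 libraries entered 1 robust quasi-likelihood fit without covariates. IP was compared with PBS, IV with PBS and IP with IV, and the last is also the test of the difference between the effects of the routes. Tests were two-sided, and p-values were adjusted by Benjamini and Hochberg over the genes tested, with a threshold of 0.05. Fold changes are log2 and given as first group minus second, with an approximate standard error, the absolute log2 fold change divided by the square root of the F statistic. CPM in the text are TMM-scaled and given as mean ± SD over the 3 libraries of a group.

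The tests, the groups entering them, 36 gene lists (596 entries), the rule for naming genes and 17 of the alternative settings were fixed before the data were examined, while 4 settings, on acinar transcripts and depth, were added later. Genes named are, for each comparison, the 12 largest rises and the 12 largest falls among genes past the threshold with a mean of at least 5 CPM, a symbol that is not a provisional, pseudogene, immunoglobulin or receptor segment name, and groups that do not overlap, up to 4 members with the smallest p of each list, and 14 genes plus the OT-I receptor segments named whatever their result. The 11 genes called in opposite directions were named after their values were seen where this rule does not cover them. Some genes that the rule covers are not reported here and are left out of the named results, while they stay in the fit and in the lists. Lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01 and adjusted over all lists and comparisons. With a correlation estimated for each list, all 66 calls of a list in 1 comparison were lost, so the list tests rest on the preset. Beside the members called over all genes, the number adjusted over the list alone is given. Lists share some members, and the OT-I segment list spells 1 gene in 2 ways.

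The rules that sort the explanation tests of the closing part were completed after their values were known, without changing how any of them was sorted. An exception is the test of a rise of acinar genes with the treatment, which first rested on IV 4 alone and counted against it, and was then replaced by a count over all treated libraries, which leaves it open.

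The scripts were tested on simulated counts drawn from the real means and library sizes, with known changes in 200 of 17123 genes. With few changed genes the adjustment is stricter, so the shares recovered do not give the sensitivity of the real comparisons. Of the genes changed by 1.5, 2 and 4-fold the test recovered 4.48%, 29.9% and 71.2% for IP against PBS, with 6 false calls among 76, 1.49%, 43.3% and 78.8% for IV against PBS, with 8 among 90, and 4.48%, 40.3% and 72.7% for IP against IV, with 7 among 85. Alternatives were DESeq2 1.42.0 (size factors in edgeR, and its Wald test), limma voom, limma on the deposited log2 CPM, other filters, fits of only the groups compared, the replicate number as a block, each library left out in turn, and the added settings. Library totals of 7379798 to 44626843 counts set the precision, the shallowest being IV 2. The p-values measure the spread between mice within groups of 3, for which a rank test alone could not go below 0.10.

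Genes with near-identical copies, such as the Gbp, H2, Ly6, Klra, Trbv12, hemoglobin and trypsin families, share reads that counting may have split, and overlapping or antisense genes may share them too, so their values are uncertain. Poly(A) selection leaves out transcripts without a tail. A fold change is not given against a group whose libraries are all at 0.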

Results

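RNA sequencing was carried out on the omenta of 9 C57BL/6 mice that carried B16-OVA tumours. The omentum is a fatty fold of the abdominal lining in which tumour cells of the peritoneal cavity settle, and B16-OVA is a mouse melanoma line made to express chicken ovalbumin. On day 6 after tumour injection the mice received saline (PBS) or OT-I T cells, whose receptor recognises an ovalbumin peptide, and tissue was taken 18 h later. The T cells had been electroporated with mRNA coding for IL-12, a cytokine that drives interferon-gamma production, and were given into the peritoneal cavity (IP) or into the blood (IV). Each group had 3 libraries, each labelled with a separate mouse number: PBS 1, PBS 2 and PBS 3, IP 2, IP 3 and IP 4, and IV 1, IV 2 and IV 4. Total counts were 34369342, 25993996 and 44626843 in the PBS libraries, in the same order. The IP libraries had 32292732, 25409924 and 31292890 counts, and the IV libraries 29243565, 7379798 and 41146527. The design addresses how local and systemic delivery of the T cells change the tumour-bearing omentum. The sample titles give no route for PBS, so differences between IP and IV may include those of the injection itself. No group received T cells without IL-12 mRNA, so effects of the cells and of the mRNA cannot be told apart.

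The first principal component of the 1000 most variable genes held 60.4% of their variance and ran from -64.3 in PBS 1 to 62.3 in IP 4. IV 4 scored -23.3 on it, between the PBS libraries and the scores of 33.5 in IV 1 and 22.3 in IV 2. Across genes, which are not independent replicates, the log2 CPM of IV 4 correlated with PBS 3 at r = 0.982, with IV 1 at 0.948 and with IV 2 at 0.953. For IV 4, r was 0.9582 with PBS 1, 0.9589 with PBS 2, 0.9575 with IP 2, 0.9598 with IP 3 and 0.9454 with IP 4. IV 1 correlated with IP 4 at 0.9645 and with IV 2 at 0.9643. Genes of the pancreatic acinar list, which encode digestive enzymes, took 2.87% of the counts of IV 1, 2.13% of IP 4 and 0.538% of IV 2, against 0.0219% of IP 2, 0.0272% of IP 3, 0.00127% of IV 4 and 0.00162% to 0.0023% of the PBS libraries. Mitochondrial genes took 1.71% to 1.9% of the counts in the IP libraries, 2.16% to 2.25% in IV and 2.27% to 3.09% in PBS, without overlap between the groups. As a check for repeated libraries, the counts of pairs within a group were set against sampling noise, with a smallest chi-square per degree of freedom of 7.09 (IP 2 with IP 3), and none was treated as a repeat.

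After IP delivery the omentum held far more transcripts of effector cytokine, cytotoxicity and inflammation genes than after PBS. Ifng, which encodes interferon-gamma, averaged 715 ± 131 CPM (SD, n = 3) in IP and 0.826 ± 0.656 CPM in PBS, a log2 fold change of 9.74 ± 0.73 (SE; edgeR adjusted p = 2.73e-05). Gzmb, the gene of the cytotoxic granule protease granzyme B, averaged 565 ± 37 and 5.35 ± 3.74 CPM (log2 fold change 6.71 ± 0.53, adjusted p = 2.67e-05). Nos2, the inducible nitric oxide synthase of activated macrophages, averaged 537 ± 51.7 and 2.24 ± 1.5 CPM (7.87 ± 1.01, adjusted p = 0.000707). Arg1, which encodes the arginine-degrading enzyme arginase 1, rose from 40.7 ± 13.1 to 1310 ± 210 CPM (5.01 ± 0.84, adjusted p = 0.00218). Thrsp, a gene of fatty acid synthesis, fell from 33.8 ± 14.6 to 2.33 ± 0.551 CPM (-3.87 ± 0.37, adjusted p = 4.55e-05). The largest rises also included Ptgs2, the inducible prostaglandin synthase (6.20 ± 0.51), Il1rn, the interleukin-1 receptor antagonist (6.09 ± 0.61), and the pattern recognition molecule Ptx3 (6.08 ± 0.49), with adjusted p-values of at most 0.00011. In all, 5626 of 17123 tested genes passed the test, 3197 higher and 2429 lower in IP, and the lower count was 1602 without PBS 1 and 1602 without IP 2. Higher genes made up 56.8% of the calls on the counts. When limma was run on the deposited log2 CPM they made up 42.6%, and there the median of all genes lay at -0.14.

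**Figure D1:**
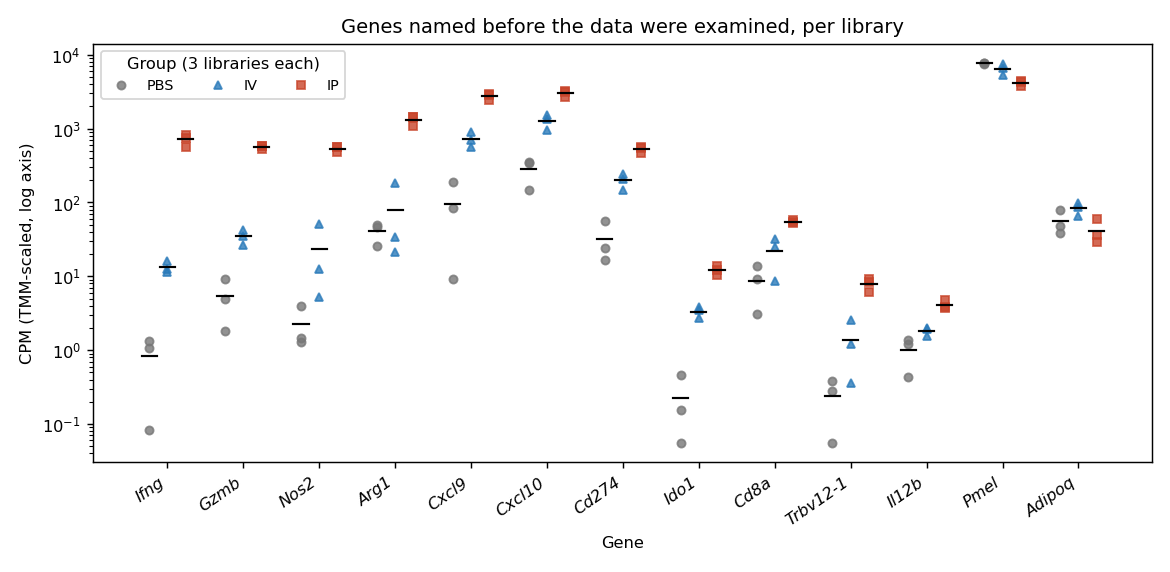
CPM (TMM-scaled, log axis) of 13 genes named before the data were examined, with 1 point per library and a line at the mean of the 3 libraries of PBS, IV or IP. Ifng averaged 0.826 CPM in PBS, 13.3 CPM in IV and 715 CPM in IP, and Pmel 7680, 6450 and 4160 CPM.

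Interferon-responsive and antigen presentation genes rose as groups after IP delivery. All 30 members of the interferon-gamma response list rose (30 adjusted over the list alone), with a median log2 fold change of 3.60 (camera adjusted p = 4.71e-20, adjusted p = 0.226 with an estimated correlation). Cxcl10, a chemokine that attracts activated T cells, went from 282 ± 116 to 3000 ± 267 CPM (3.42 ± 0.32, adjusted p = 4.05e-05). Cd274, which encodes the inhibitory ligand PD-L1, went from 32.4 ± 21.3 to 522 ± 52.5 CPM (4.01 ± 0.42, adjusted p = 6.65e-05). Ido1, a tryptophan-degrading enzyme, went from 0.225 ± 0.216 to 12.2 ± 1.75 CPM (5.62 ± 0.50, adjusted p = 3.4e-05). All 24 members of the type I interferon response list rose (24 adjusted over the list alone), with a median of 2.93 (camera adjusted p = 4.59e-31, adjusted p = 0.182 with an estimated correlation), among them the antiviral genes Mx2 (3.07 ± 0.24) and Oasl1 (2.89 ± 0.24). All 19 genes of MHC class I presentation rose (19 adjusted over the list alone), with a median of 2.29 (camera adjusted p = 6.04e-15, adjusted p = 0.226 with an estimated correlation), including B2m, the class I light chain (1.63 ± 0.20). Of 11 MHC class II genes, 8 rose, 0 fell and 3 did not pass (8 and 0 adjusted over the list alone), and Cd74, the class II invariant chain, rose by 2.11 ± 0.36 (adjusted p = 0.00121). Over the 11 genes the median was 1.89 (camera adjusted p = 7.03e-05, adjusted p = 0.383 with an estimated correlation). Cxcl9, another interferon-induced chemokine, averaged 2750 ± 252 CPM in IP and 94 ± 90.2 CPM in PBS (4.87 ± 0.95, adjusted p = 0.00566). In the same libraries Xist, transcribed from the inactive X chromosome of female cells, was higher in IP by 1.07 ± 0.31 (adjusted p = 0.0215, up to 0.0798 without PBS 1, PBS 2 or IP 4, and 0.143 with no filter).

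Cytotoxic and T cell genes also rose after IP delivery. Of 25 cytotoxic and type 1 effector genes, 22 rose and 0 fell (23 and 0 adjusted over the list alone), among them the pore-forming protein gene Prf1 (4.53 ± 0.48, adjusted p = 8.67e-05). For all 25 together the median was 2.44 (camera adjusted p = 2.21e-14, adjusted p = 0.282 with an estimated correlation). Of 22 T cell markers, 17 rose and 0 fell (19 and 1 adjusted over the list alone), and 1 was called lower without IV 1. Across these 22 genes the median was 1.70 (camera adjusted p = 5.31e-06, adjusted p = 0.466 with an estimated correlation). Cd3e, a T cell receptor subunit, averaged 23.2 ± 1.59 CPM in IP and 5.85 ± 3.24 CPM in PBS (1.98 ± 0.40, adjusted p = 0.00322). Cd8a, the marker of the transferred T cell class, averaged 55.1 ± 3.03 and 8.62 ± 5.3 CPM (2.67 ± 0.56, adjusted p = 0.00557, and 0.056 with no filter on low counts). Trbv12-1, a beta chain segment of the family used by the OT-I receptor, averaged 7.89 ± 1.51 and 0.241 ± 0.169 CPM (5.05 ± 0.71, adjusted p = 0.000358). Its near-identical neighbour Trbv12-2 averaged 0.232 ± 0.15 and 0.536 ± 0.376 CPM (-1.15 ± 0.81, adjusted p = 0.311). These 2 were the only tested members of the OT-I receptor segment list, whose camera adjusted p was 0.369. The others had too few counts to be tested. The alpha chain segment Trav14-1 had 0, 0 and 2 counts in IP and 4, 2 and 2 in PBS. Trav14-2 had 2, 3 and 1 in IP and 3, 3 and 5 in PBS, and Trav14-3 0, 0 and 0 and 0, 0 and 2. Trav14d-3-dv8 had 3, 4 and 0 in IP and 0, 5 and 15 in PBS, and Trbj2-7 3, 8 and 5 and 4, 2 and 13. Trav14d-1, Trav14d-2 and Traj33 had none in either group. Il12b, which encodes the p40 chain of IL-12, averaged 4.11 ± 0.584 and 1.02 ± 0.507 CPM (2.01 ± 0.38, adjusted p = 0.00237). Il12a had 10, 5 and 4 counts in the IP libraries and 3, 1 and 4 in the PBS libraries, too few to be tested. Counts of these genes do not tell transcripts of the mice from the delivered mRNA, whose sequence is not given in the sources used here.

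Genes of myeloid cells and of their chemoattractants rose in the IP omenta. Of 28 tested chemokine genes, 25 rose and 1 fell (25 and 1 adjusted over the list alone). Over the 28 genes the median was 3.62 (camera adjusted p = 6.44e-22, adjusted p = 0.182 with an estimated correlation). Ccl2, which attracts monocytes, averaged 276 ± 42.4 CPM in IP and 9.31 ± 4.72 CPM in PBS (4.89 ± 0.38, adjusted p = 2.45e-05). All 18 tested inflammatory cytokine genes rose (18 adjusted over the list alone), such as Osm, the gene of oncostatin M (4.10 ± 0.33). For all 18 together the median was 3.42 (camera adjusted p = 7.85e-16, adjusted p = 0.182 with an estimated correlation). Of 17 tested neutrophil markers, 14 rose and 0 fell (14 and 0 adjusted over the list alone), including the chemokine receptor gene Cxcr2 (4.28 ± 0.43) and Lcn2 (4.23 ± 0.54). Across these 17 genes the median was 3.40 (camera adjusted p = 1.95e-07, adjusted p = 0.254 with an estimated correlation). Of 12 monocyte markers, 9 rose and 0 fell (9 and 0 adjusted over the list alone), including Fcgr1, a high-affinity antibody receptor (2.85 ± 0.36). Over the 12 genes the median was 2.28 (camera adjusted p = 2.99e-07, adjusted p = 0.218 with an estimated correlation). Of 15 tested alternative activation genes, 10 rose and 2 fell (10 and 2 adjusted over the list alone), and 1 fell without PBS 1, PBS 3, IP 2 or IP 3. For all 15 together the median was 2.75 (camera adjusted p = 2.82e-07, adjusted p = 0.182 with an estimated correlation). Tgm2, a transglutaminase gene of that list, rose by 3.63 ± 0.28. Of 20 checkpoint and costimulation genes, 18 rose and 0 fell (19 and 0 adjusted over the list alone), with Pdcd1lg2, the gene of the inhibitory ligand PD-L2, up by 5.51 ± 0.43 and Tnfrsf9, the gene of the costimulatory receptor 4-1BB, up by 4.53 ± 0.39. Across these 20 genes the median was 2.56 (camera adjusted p = 8.14e-17, adjusted p = 0.182 with an estimated correlation).

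Lipid synthesis, pigment cell and cell division genes fell after IP delivery. Of 15 tested lipogenesis genes, 0 rose and 12 fell (0 and 12 adjusted over the list alone). Over the 15 genes the median was -1.78 (camera adjusted p = 5.15e-10, adjusted p = 0.218 with an estimated correlation). Fasn, the fatty acid synthase gene, went from 523 ± 173 to 119 ± 15 CPM (-2.13 ± 0.25, adjusted p = 0.000116). Elovl6, a fatty acid elongase, went from 69.4 ± 12.5 to 12.6 ± 1.39 CPM (-2.47 ± 0.16, adjusted p = 1.25e-05). Pck1, a gene of glycerol and glucose synthesis, went from 19.7 ± 14.8 to 0.715 ± 0.565 CPM (-4.82 ± 0.80, adjusted p = 0.00155). Of 16 melanoma and pigment genes, 0 rose and 11 fell (0 and 11 adjusted over the list alone). For all 16 together the median was -0.89 (camera adjusted p = 2.42e-06, adjusted p = 0.292 with an estimated correlation). Pmel, a melanosome protein gene, averaged 4160 ± 292 CPM in IP and 7680 ± 91.8 CPM in PBS (-0.89 ± 0.14, adjusted p = 0.000824). Tyr, the tyrosinase gene of melanin synthesis, averaged 298 ± 19.7 and 1040 ± 128 CPM (-1.80 ± 0.18, adjusted p = 4.92e-05). All 25 proliferation genes fell (25 adjusted over the list alone), among them the mitotic kinase genes Bub1 (-1.63 ± 0.13) and Plk1 (-1.29 ± 0.13). Across these 25 genes the median was -1.13 (camera adjusted p = 7.85e-16, adjusted p = 0.218 with an estimated correlation). Adipoq, the adipocyte hormone adiponectin, averaged 41.6 ± 16 and 55.3 ± 22 CPM, a difference that did not pass (-0.41 ± 0.31, adjusted p = 0.346).

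**Figure D2:**
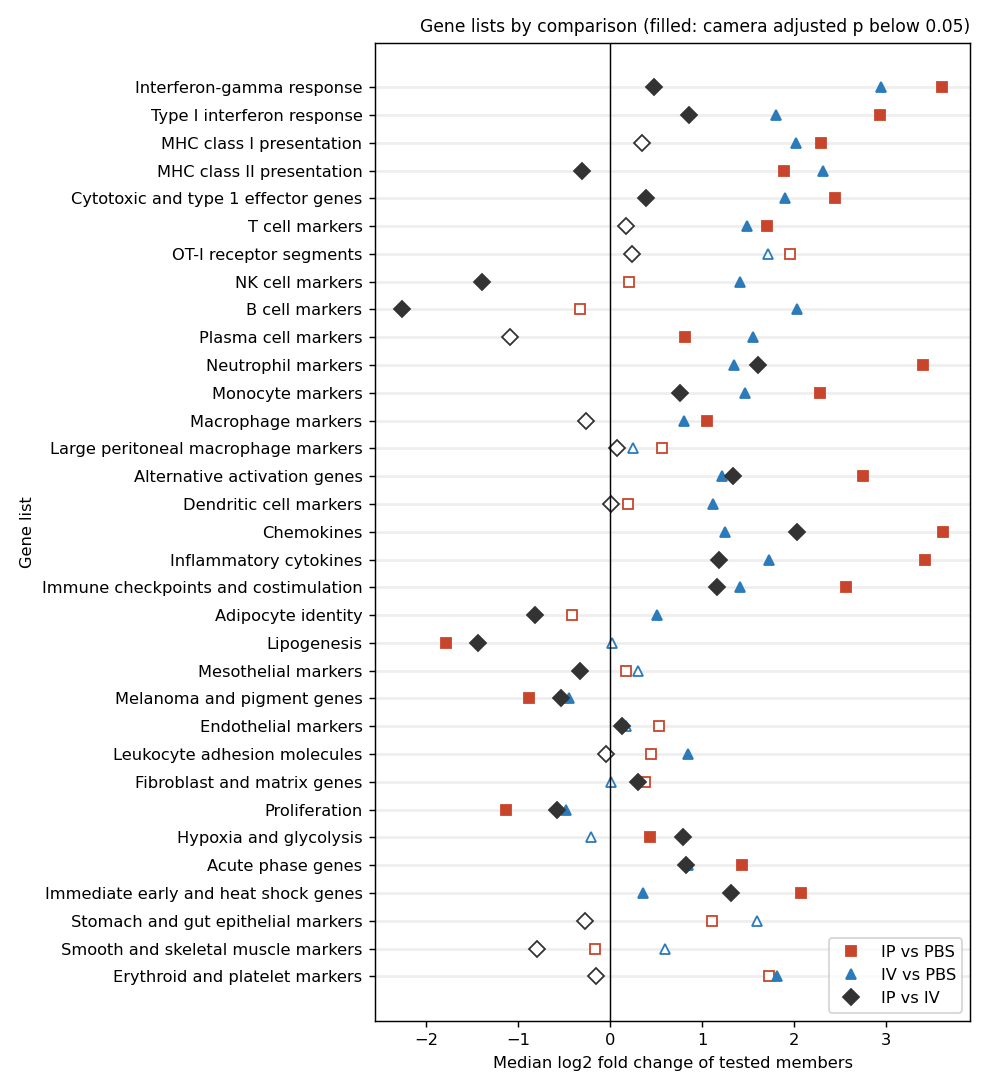
Median log2 fold change of the tested members of 33 gene lists in IP against PBS (squares), IV against PBS (triangles) and IP against IV (diamonds), filled where camera with its preset correlation gave an adjusted p below 0.05. With an estimated correlation none passed, and the acinar, IL-12 and sex-linked lists are not plotted. The interferon-gamma response list lay at 3.60 in IP and 2.94 in IV against PBS, and the B cell list at -0.33 and 2.03.

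Markers of other cell types were also compared between IP and PBS. Of 17 B cell markers, 0 rose and 2 fell (0 and 1 adjusted over the list alone), namely Fcer2a (-2.45 ± 0.53, adjusted p = 0.00502, and not called with counts thinned to the depth of IV 2) and Cr2 (-1.49 ± 0.51, adjusted p = 0.0458). Over the 17 genes the median was -0.33 (camera adjusted p = 0.166). The call of Cr2 was lost without any 1 of the PBS or IP libraries (adjusted p up to 0.143), and 1 B cell marker was called higher without IV 2. Of 13 tested NK cell markers, 3 rose and 0 fell (3 and 0 adjusted over the list alone), and 1 rose without PBS 2, while 1 was called lower without PBS 1 or IV 1. For all 13 together the median was 0.21 (camera adjusted p = 0.607). Of 17 tested dendritic cell markers, 6 rose and 1 fell (6 and 2 adjusted over the list alone), and 2 fell without IV 1 or IV 2. Across these 17 genes the median was 0.20 (camera adjusted p = 0.0714, and as low as 0.0324 without PBS 3, IP 2 or IP 3). Of 17 macrophage markers, 9 rose and 4 fell (9 and 4 adjusted over the list alone), and 2 fell without PBS 1, IP 2 or IP 3. Over the 17 genes the median was 1.05 (camera adjusted p = 0.00784, and 0.0641 without PBS 2, with adjusted p = 0.48 with an estimated correlation). The scavenger receptor gene Msr1 rose by 2.04 ± 0.18 (adjusted p = 3.38e-05). Of 14 large peritoneal macrophage markers, 3 rose and 2 fell (3 and 2 adjusted over the list alone), with 5 higher without IV 1 and 1 lower without PBS 1, IP 3 or IP 4. For all 14 together the camera adjusted p was 0.406. Of 13 tested plasma cell markers, 6 rose and 0 fell (6 and 1 adjusted over the list alone), and 1 was called lower without IV 2. Across these 13 genes the median was 0.81 (camera adjusted p = 0.0426, up to 0.0573 without PBS 1 or IP 4 and 0.135 with the acinar level as a covariate, with adjusted p = 0.292 with an estimated correlation). Those with the smallest p-values were Prdm1, Irf4, Xbp1 and Edem1, regulators of activated lymphocytes or of the secretory pathway that other cells also express.

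Markers of tissues near the omentum were measured in the same libraries. None of the 17 tested acinar genes passed between IP and PBS in edgeR (0 adjusted over the list alone), and 11 passed without IV 4. Over the 17 genes the camera adjusted p was 0.0563, and between 0.00883 and 0.143 with 1 library left out. Pnlip, the pancreatic lipase gene, averaged 576 ± 940 CPM in IP, 1590 ± 2070 CPM in IV and 0.34 ± 0.34 CPM in PBS. In IV against PBS 0 acinar genes passed over all genes and 17 passed adjusted over the list alone (camera adjusted p = 0.00391, 0.0635 without IV 1 and 0.703 with the acinar level as a covariate, with adjusted p = 0.611 with an estimated correlation), and 5 passed without IV 4. Tff2, a mucus-associated stomach and gut peptide gene, averaged 51.3 ± 86 CPM in IP, 74.2 ± 97.6 CPM in IV and 0 CPM in PBS. The camera adjusted p of the stomach and gut epithelial list was 0.471 in IP and 0.0839 in IV against PBS, the latter reaching 0.0348 without IP 4. The muscle list had a camera adjusted p of 0.68 in IP and 0.216 in IV against PBS. The erythroid and platelet list had a median of 1.73 in IP (camera adjusted p = 0.0638, down to 0.00393 with 1 library left out). Its median was 1.81 in IV (camera adjusted p = 0.0169, up to 0.165 without PBS 2, PBS 3, IV 1 or IV 2, 0.37 with the acinar level as a covariate, with adjusted p = 0.463 with an estimated correlation). Xist was the only tested member of the sex-linked list, since the 4 genes on the Y chromosome had too few counts.

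After IV delivery the omentum also held more interferon-responsive, antigen presentation and effector transcripts than after PBS. Ifng averaged 13.3 ± 2.6 CPM (SD, n = 3) in IV and 0.826 ± 0.656 CPM in PBS (log2 fold change 3.99 ± 0.60, SE; edgeR adjusted p = 0.00362), and Gzmb 35.1 ± 7.96 and 5.35 ± 3.74 CPM (adjusted p = 0.00435). Cd274 averaged 200 ± 47.5 and 32.4 ± 21.3 CPM (2.62 ± 0.39, adjusted p = 0.003), and Cxcl10 averaged 1270 ± 278 and 282 ± 116 CPM (2.18 ± 0.30, adjusted p = 0.00251). The largest rises also included Gbp11, an interferon-induced GTPase gene (4.04 ± 0.58), Ido1 (3.74 ± 0.49) and Prph, the gene of the intermediate filament peripherin, which went from 18.6 ± 10.8 to 255 ± 82.2 CPM (3.78 ± 0.47, adjusted p = 0.00193). Among the falls were Dusp4 (-1.25 ± 0.18, adjusted p = 0.00288) and Spry4 (-1.47 ± 0.26, adjusted p = 0.0053), feedback inhibitors of growth factor signalling, and the matrix glycoprotein gene Tnc (-1.64 ± 0.22, adjusted p = 0.00208). Arg1 (78.8 ± 89.1 against 40.7 ± 13.1 CPM, adjusted p = 0.409), Il12b (1.84 ± 0.242 against 1.02 ± 0.507 CPM, adjusted p = 0.169), Pmel (6450 ± 1100 against 7680 ± 91.8 CPM, adjusted p = 0.256) and Adipoq (83.8 ± 16.4 against 55.3 ± 22 CPM, adjusted p = 0.22) did not pass. Cd8a averaged 21.8 ± 11.9 and 8.62 ± 5.3 CPM (1.33 ± 0.55, adjusted p = 0.131, and 0.0346 without IV 1). Cxcl9 averaged 715 ± 165 and 94 ± 90.2 CPM (2.93 ± 0.87, adjusted p = 0.058, and as low as 0.00356 without PBS 1 or PBS 3).

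Of 17123 genes tested, 2753 passed between IV and PBS, 1784 higher and 969 lower in IV. This count was 980 without PBS 1, 1794 without PBS 2, 1403 without IV 2 and 4580 without IV 4. With only the 2 groups compared it was 1210, and with the acinar level as a covariate 1260. The lower genes alone numbered 210 without PBS 1, 414 without IV 2, 600 without IP 2, 600 without IP 3, 609 without IV 1 and 2248 without IV 4, all 9 libraries sharing 1 estimate of spread, and 275, 284 and 1766 with only the 2 groups compared, with the acinar covariate and in the DESeq2 Wald test. Without IP 4, IV 1 and IV 2, a setting added after the data were seen that leaves a single IV library, 0 genes passed in edgeR, 612 passed in limma voom and 3691 had an unadjusted p under 0.05. Higher genes made up 64.8% of the calls on the counts (50.9% without IV 4 and 78.6% without PBS 1) and 54.6% in limma on the deposited log2 CPM. Nos2 (23.1 ± 25 against 2.24 ± 1.5 CPM, 3.36 ± 0.84, adjusted p = 0.0326) lost its call without PBS 1, PBS 2, IP 2 or IP 3, with adjusted p up to 0.144. Cd3e (1.73 ± 0.40, adjusted p = 0.0169) lost it without PBS 1, PBS 2, IV 2 or IV 4 (up to 0.0775). Trbv12-1 (2.60 ± 0.70, adjusted p = 0.0315) kept it only without IP 4 or IV 1 (up to 0.165 without the others), and Trbv12-2 had an adjusted p of 0.502. With no filter on low counts Nos2, Cd3e and Trbv12-1 all lost their calls.

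Interferon-responsive and antigen presentation genes rose as groups after IV delivery too. Of 30 interferon-gamma response genes, 28 rose and 0 fell (30 and 0 adjusted over the list alone), and 12 rose without PBS 2. For all 30 together the median was 2.94 (camera adjusted p = 3.09e-30, adjusted p = 0.182 with an estimated correlation). Among them was the stem cell antigen gene Ly6a (3.10 ± 0.38). All 24 type I interferon response genes rose (24 adjusted over the list alone), such as the antiviral genes Oas2 (1.95 ± 0.23) and Dhx58 (2.25 ± 0.27). Across these 24 genes the median was 1.80 (camera adjusted p = 1.62e-31, adjusted p = 0.182 with an estimated correlation). All 19 genes of MHC class I presentation rose (19 adjusted over the list alone), with B2m up by 1.44 ± 0.20. Over the 19 genes the median was 2.02 (camera adjusted p = 9.79e-23, adjusted p = 0.182 with an estimated correlation). All 11 MHC class II genes rose (11 adjusted over the list alone), with H2-Aa, a class II chain, going from 214 ± 108 to 1060 ± 229 CPM (2.31 ± 0.36, adjusted p = 0.00342). For all 11 together the median was 2.31 (camera adjusted p = 1.98e-15, adjusted p = 0.182 with an estimated correlation). Xist was higher in IV than in PBS by 1.22 ± 0.31 (adjusted p = 0.0245, up to 0.0943 without PBS 1, PBS 2, IV 2 or IV 4, and 0.136 with no filter).

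Lymphocyte groups and some myeloid groups rose in IV as well, with counts that depended on single libraries. All 17 B cell markers rose (17 adjusted over the list alone), 8 of them without PBS 1 and 10 without PBS 2. Across these 17 genes the median was 2.03 (camera adjusted p = 1.86e-11, adjusted p = 0.292 with an estimated correlation). Ms4a1, the gene of the B cell surface protein CD20, averaged 48.3 ± 33.9 CPM in IV and 10.4 ± 0.373 CPM in PBS (2.20 ± 0.43, adjusted p = 0.00826, and 0.06 with no filter on low counts). Of 13 tested plasma cell markers, 7 rose and 1 fell (9 and 1 adjusted over the list alone), including the antibody genes Igha (1.85 ± 0.31) and Iglv1 (2.50 ± 0.29), with 3 higher without PBS 2, 4 higher without IV 2 and 0 lower without PBS 1 or IV 2. Over the 13 genes the median was 1.55 (camera adjusted p = 5.81e-05, adjusted p = 0.182 with an estimated correlation). Of 22 T cell markers, 15 rose and 0 fell (20 and 0 adjusted over the list alone), but 3 without IV 2, 4 without PBS 1, 6 without PBS 2 and 8 without IV 4. For all 22 together the median was 1.49 (camera adjusted p = 1.33e-10, adjusted p = 0.334 with an estimated correlation). The median level of the list in IV 1 (3.09, log2 CPM) lay within the PBS range (1.91 to 3.27), while IV 2 (4.54) and IV 4 (4.61) lay above it. Of 25 cytotoxic genes, 22 rose and 0 fell (25 and 0 adjusted over the list alone), and 10 rose without PBS 2, 12 without PBS 1 and 12 without IV 2. Across these 25 genes the median was 1.90 (camera adjusted p = 5.97e-18, adjusted p = 0.226 with an estimated correlation). Of 13 tested NK cell markers, 7 rose and 0 fell (7 and 0 adjusted over the list alone), with 2 higher without PBS 1 or IV 2, 3 without PBS 2, and 4 without IP 2 or IP 3. Over the 13 genes the median was 1.41 (camera adjusted p = 3.77e-05, adjusted p = 0.428 with an estimated correlation). Of 17 tested dendritic cell markers, 9 rose and 0 fell (10 and 0 adjusted over the list alone), with 4 higher without PBS 1 and 5 without PBS 2 or IV 2, and Clec9a, a receptor of cross-presenting dendritic cells, rose by 2.47 ± 0.33 (adjusted p = 0.00216). For all 17 together the median was 1.12 (camera adjusted p = 0.000101, adjusted p = 0.334 with an estimated correlation). Of 12 monocyte markers 8 rose (8 adjusted over the list alone), and 1 was called lower without PBS 2. Across these 12 genes the median was 1.47 (camera adjusted p = 7.96e-07, adjusted p = 0.226 with an estimated correlation). Of 17 macrophage markers 7 rose (7 adjusted over the list alone), including the complement genes C1qa, C1qb and C1qc (1.56 ± 0.23, 1.66 ± 0.24 and 1.53 ± 0.23). Over the 17 genes the median was 0.80 (camera adjusted p = 2.18e-05, adjusted p = 0.292 with an estimated correlation). Of 14 large peritoneal macrophage markers 2 rose and 0 fell (2 and 0 adjusted over the list alone). With 1 library left out, 0 to 3 rose, and 1 was called lower without IV 1. For all 14 together the median was 0.25 (camera adjusted p = 0.649). Neutrophil markers, of which 2 of 17 tested rose, are described with the routes.

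Chemokine, cytokine and checkpoint genes rose in IV, and proliferation genes fell. Of 28 tested chemokine genes, 16 rose and 0 fell (20 and 0 adjusted over the list alone), and 1 was called lower without IV 1. For all 28 together the median was 1.25 (camera adjusted p = 6.6e-12, adjusted p = 0.226 with an estimated correlation). Ccl7, which attracts monocytes, averaged 37 ± 6.85 CPM in IV and 6.45 ± 3.21 CPM in PBS (2.51 ± 0.33, adjusted p = 0.00208). Of 18 tested cytokine genes, 13 rose and 0 fell (15 and 0 adjusted over the list alone), and 8 rose without IV 2. Across these 18 genes the median was 1.73 (camera adjusted p = 1.13e-12, adjusted p = 0.182 with an estimated correlation). Il15, a survival factor of NK and CD8 T cells, rose by 1.74 ± 0.21, and Il18bp, a secreted inhibitor of interleukin-18, by 3.23 ± 0.45. Of 20 checkpoint and costimulation genes, 13 rose and 0 fell (15 and 0 adjusted over the list alone), and 8 rose without PBS 2 or IV 2. Over the 20 genes the median was 1.41 (camera adjusted p = 3.41e-13, adjusted p = 0.218 with an estimated correlation). Of 25 proliferation genes, 0 rose and 14 fell (0 and 19 adjusted over the list alone), with 5 lower without PBS 1 and 9 without IV 1, and Bub1 fell by 0.90 ± 0.13 (adjusted p = 0.00271). For all 25 together the median was -0.48 (camera adjusted p = 1.19e-09, adjusted p = 0.292 with an estimated correlation). Of 16 melanoma and pigment genes, 0 rose and 7 fell (0 and 8 adjusted over the list alone), with 2 lower without PBS 1, 3 without IV 2 and 4 without IP 4. Across these 16 genes the median was -0.45 (camera adjusted p = 0.000743, adjusted p = 0.446 with an estimated correlation).

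**Figure D3:**
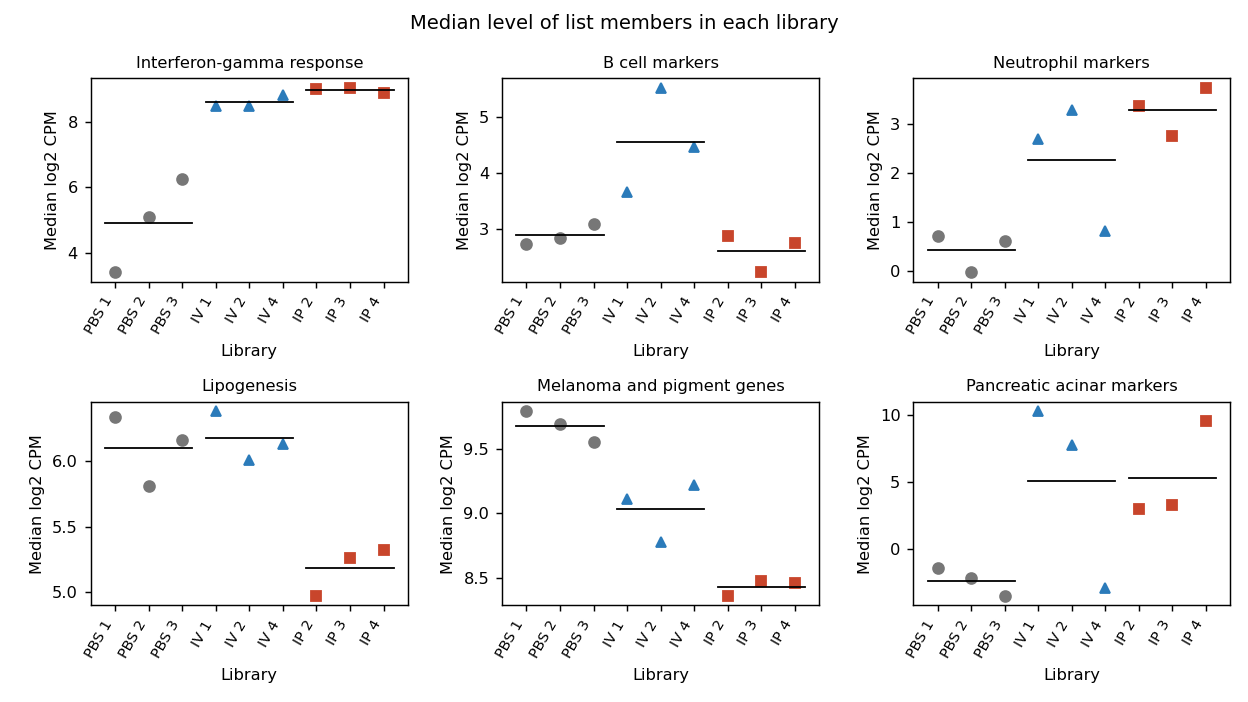
Median log2 CPM of the tested members of 6 gene lists in each library (points, log2 axes that do not start at 0), with a line at the mean of each group of 3. The B cell medians of all 3 IV libraries lie above those of PBS and IP, and the acinar medians are highest in IV 1, IP 4 and IV 2.

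Between the routes, IP omenta held more transcripts of effector, chemokine and neutrophil genes and IV omenta more B cell and lipid synthesis transcripts. Ifng was higher in IP (715 ± 131 CPM, SD, n = 3) than in IV (13.3 ± 2.6 CPM) by a log2 fold change of 5.76 ± 0.61 (SE; edgeR adjusted p = 0.000824), and Gzmb (565 ± 37 and 35.1 ± 7.96 CPM) by 4.01 ± 0.47 (adjusted p = 0.000861). Ptx3 averaged 148 ± 20.3 and 4.31 ± 2.83 CPM (5.03 ± 0.47, adjusted p = 0.000366). Ccl3, a chemokine of activated macrophages and T cells, averaged 61.4 ± 6 and 2.99 ± 0.119 CPM (4.35 ± 0.50, adjusted p = 0.000824). Thrsp was lower in IP (2.33 ± 0.551 CPM) than in IV (71.9 ± 20.4 CPM), at -4.95 ± 0.39 (adjusted p = 0.000135), as was Ms4a1 (8.25 ± 1.89 and 48.3 ± 33.9 CPM, -2.53 ± 0.44, adjusted p = 0.00525). Igfbp5, an insulin-like growth factor binding protein gene, averaged 18.4 ± 6.56 and 154 ± 41.7 CPM (-3.06 ± 0.34, adjusted p = 0.000762). In all, 1780 of 17123 genes passed, 1015 higher and 765 lower in IP, and 673 passed without IP 2, 791 without IP 3, 1058 without IP 4, 2873 without IV 4 and 2759 in the DESeq2 Wald test. Without IP 4, IV 1 and IV 2 together, a setting added after the data were seen, 598 passed, 484 of them among the 1780. Higher genes made up 57% of the calls on the counts and 40.7% in limma on the deposited log2 CPM, on which the median of all genes lay at -0.11.

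Chemokine, cytokine and neutrophil genes differed between the routes. Of 28 tested chemokine genes, 20 were higher and 1 lower in IP (21 and 2 adjusted over the list alone), with 13 higher without IP 2 and 2 lower without IV 4. Over the 28 genes the median was 2.03 (camera adjusted p = 7.08e-19, adjusted p = 0.182 with an estimated correlation). Ccl2 averaged 276 ± 42.4 CPM in IP and 32.6 ± 6.37 CPM in IV (3.08 ± 0.35, adjusted p = 0.000824). Of 18 tested cytokine genes, 9 were higher and 1 lower (10 and 1 adjusted over the list alone), with 0 lower without IP 2, IP 3, IP 4, IV 1 or IV 2, and Lif, the gene of leukemia inhibitory factor, was higher by 2.64 ± 0.31. For all 18 together the median was 1.18 (camera adjusted p = 2.14e-08, adjusted p = 0.182 with an estimated correlation). Of 17 tested neutrophil markers, 6 were higher and 0 lower (9 and 0 adjusted over the list alone), with Cxcr2 at 12.8 ± 1.63 and 0.769 ± 0.363 CPM (4.22 ± 0.45, adjusted p = 0.000625). Across these 17 genes the median was 1.61 (camera adjusted p = 4.16e-07, adjusted p = 0.268 with an estimated correlation). In IV against PBS 2 neutrophil markers had passed (3 adjusted over the list alone; camera adjusted p = 0.00272, 0.0635 without IV 1 and 0.153 with the acinar level as a covariate, with adjusted p = 0.463 with an estimated correlation), a count between 0 and 4 with 1 library left out. Of 12 monocyte markers, 1 was higher and 0 lower (3 and 0 adjusted over the list alone), with 4 higher without PBS 1, 2 without PBS 2, and 3 higher and 1 lower without PBS 3. Over the 12 genes the camera adjusted p was 0.00259, adjusted p = 0.444 with an estimated correlation. The gene called was Vcan, which encodes a matrix proteoglycan (1.61 ± 0.18). Of 15 tested alternative activation genes, 7 were higher and 1 lower (8 and 3 adjusted over the list alone), with 0 lower without IP 2, IP 3 or IV 4 and 2 lower without PBS 3 or IP 4, and Tgm2 was higher by 2.20 ± 0.26. For all 15 together the median was 1.33 (camera adjusted p = 0.000105, adjusted p = 0.226 with an estimated correlation). In IV against PBS 7 of these 15 had risen and 0 had fallen (9 and 0 adjusted over the list alone), with 3 higher without PBS 1 or IV 2 and 4 without PBS 2. Their median there was 1.21 (camera adjusted p = 1.35e-05, adjusted p = 0.182 with an estimated correlation). Other myeloid lists did not pass between the routes: macrophage markers had a median of -0.27 (camera adjusted p = 0.856). Dendritic cell markers had a median of 0.01 and a mean of -0.42 (camera adjusted p = 0.308, and 0.0097 without IV 1), and large peritoneal macrophage markers a median of 0.07 (camera adjusted p = 0.426, and 0.0122 without IV 1). Of 18 hypoxia and glycolysis genes, 8 were higher and 0 lower (10 and 0 adjusted over the list alone), such as Vegfa, a growth factor of blood vessels (1.83 ± 0.19), and Egln3, an oxygen sensor (3.34 ± 0.41). Across these 18 genes the median was 0.79 (camera adjusted p = 9.59e-13, adjusted p = 0.182 with an estimated correlation). Nos2 (4.51 ± 0.86, adjusted p = 0.0156) lost its call without IP 2, IP 3 or IV 4 (up to 0.0558), and Arg1 (4.06 ± 0.80, adjusted p = 0.016) without IP 2 or IP 3 (up to 0.0587). Both also lost it with no filter on low counts.

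B cell and lipid genes were lower in IP than in IV. Of 17 B cell markers, 0 were higher and 16 lower in IP (0 and 17 adjusted over the list alone), and 10 were lower without IP 3. Over the 17 genes the median was -2.26 (camera adjusted p = 6.33e-20, adjusted p = 0.218 with an estimated correlation). Fcer2a, the low-affinity IgE receptor gene of B cells, averaged 0.291 ± 0.111 CPM in IP and 8.06 ± 5.39 CPM in IV (-4.74 ± 0.54, adjusted p = 0.000824). Fcmr, an IgM receptor gene, averaged 3.54 ± 0.546 and 25.8 ± 17.7 CPM (-2.83 ± 0.42, adjusted p = 0.00259). Of 15 tested lipogenesis genes, 0 were higher and 10 lower (0 and 13 adjusted over the list alone), with Fasn at 119 ± 15 and 445 ± 65.4 CPM (-1.90 ± 0.24, adjusted p = 0.0013). For all 15 together the median was -1.44 (camera adjusted p = 1.5e-18, adjusted p = 0.182 with an estimated correlation). In IV against PBS the lipogenesis list had a median of 0.02 and a camera adjusted p of 0.415 (0.0315 without PBS 2), while its member Elovl6 fell by 0.80 ± 0.15 (adjusted p = 0.00721). Of 19 tested adipocyte identity genes, 0 were higher and 5 lower in IP than in IV (1 and 9 adjusted over the list alone), with 2 lower without IP 2, 3 without IP 3 and 9 without PBS 3, and 1 higher without PBS 2. Across these 19 genes the median was -0.81 (camera adjusted p = 5.26e-06, adjusted p = 0.334 with an estimated correlation). Retn, the resistin gene, was lower by -1.33 ± 0.23 (adjusted p = 0.00588), and Adipoq differed by -1.01 ± 0.31 (adjusted p = 0.067, and as low as 0.0333 without PBS 3 or IP 4). Of 25 proliferation genes, 0 were higher and 12 lower (0 and 19 adjusted over the list alone), with 4 lower without IP 2, 5 without IP 3 or IP 4, 7 without IV 2 and 19 without IV 4. Over the 25 genes the median was -0.58 (camera adjusted p = 5.37e-10, adjusted p = 0.292 with an estimated correlation). Of 16 melanoma and pigment genes, 6 were lower and 0 higher (12 and 0 adjusted over the list alone), 2 of them without IP 2. For all 16 together the median was -0.54 (camera adjusted p = 0.000128, adjusted p = 0.397 with an estimated correlation). Tyr was lower by -0.99 ± 0.17 (adjusted p = 0.00578), and Pmel by -0.63 ± 0.14 (adjusted p = 0.0176, and up to 0.115 without IP 2, IP 3, IP 4 or IV 1).

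Interferon, presentation, lymphocyte and checkpoint groups were compared between the routes as well. Of 30 interferon-gamma response genes, 6 were higher and 0 lower in IP (7 and 0 adjusted over the list alone), with 0 higher without IP 2 or IP 3, 1 without IV 4, 2 without IV 2, 3 without IP 4 or IV 1 and 10 without PBS 1, and 1 lower without PBS 3. Across these 30 genes the median was 0.47 (camera adjusted p = 0.00168, adjusted p = 0.629 with an estimated correlation). The camera call was also lost with the replicate number as a block. Of 24 type I interferon response genes, 10 were higher and 0 lower (20 and 0 adjusted over the list alone), with 5 higher without IP 2, IP 3 or IV 2, 6 without IV 1 and 17 without PBS 1, and Mx2 was higher by 1.72 ± 0.23 (adjusted p = 0.00155). Over the 24 genes the median was 0.86 (camera adjusted p = 8.02e-12, adjusted p = 0.292 with an estimated correlation). None of 19 genes of MHC class I presentation passed in edgeR (0 adjusted over the list alone), and 2 passed without PBS 1. For all 19 together the median was 0.35 (camera adjusted p = 0.0563, as low as 0.00609 without PBS 1, PBS 3 or IP 4, and below 0.05 with acinar genes left out). Of 11 MHC class II genes, 0 were higher and 3 lower (1 and 3 adjusted over the list alone), with 1 lower without IP 3 and 1 higher without PBS 1 or PBS 3. Across these 11 genes the median was -0.31 (camera adjusted p = 0.0283, up to 0.0759 without IP 3 or IV 4, with adjusted p = 0.609 with an estimated correlation). Among the 3 lower was H2-Ob (-2.22 ± 0.41, adjusted p = 0.00744), a gene mostly expressed by B cells. Of 22 T cell markers, 0 were higher and 2 lower (0 and 2 adjusted over the list alone), with 0 lower without IP 2, 1 lower without IP 3 or IP 4 and 1 higher without IV 4. Over the 22 genes the median was 0.17 (camera adjusted p = 0.696). Of 25 cytotoxic genes, 7 were higher and 0 lower (8 and 0 adjusted over the list alone), and 2 were called lower without IV 1. For all 25 together the median was 0.39 (camera adjusted p = 0.000262, and 0.115 without IV 1, with adjusted p = 0.567 with an estimated correlation). Of 13 tested NK cell markers, 0 were higher and 1 lower (0 and 8 adjusted over the list alone), with 0 lower without IP 2 or IP 3, 3 without PBS 3, 5 without IV 1 and 6 without PBS 1. Across these 13 genes the median was -1.39 (camera adjusted p = 0.000289, adjusted p = 0.463 with an estimated correlation). Of 20 checkpoint and costimulation genes, 9 were higher and 0 lower (13 and 1 adjusted over the list alone), with 5 higher without IP 2 or IP 3 and 1 lower without IV 1, and Tnfrsf9 was higher by 3.16 ± 0.37 (adjusted p = 0.000824). Over the 20 genes the median was 1.16 (camera adjusted p = 5.15e-10, adjusted p = 0.282 with an estimated correlation). Cd3e (adjusted p = 0.74) and Trbv12-2 (adjusted p = 0.157) did not pass. Neither did Cd8a (1.34 ± 0.54, adjusted p = 0.153), Cxcl9 (1.94 ± 0.83, adjusted p = 0.192, and 0.0031 without PBS 1) or Il12b (1.17 ± 0.38, adjusted p = 0.079, and 0.0247 without PBS 1).

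Some calls between the routes depended on single libraries. Trbv12-1 was higher in IP by 2.45 ± 0.61 (adjusted p = 0.0288, and up to 0.11 without IP 2, IP 3, IP 4 or IV 2), and Ido1 by 1.89 ± 0.41 (adjusted p = 0.015, and up to 0.0721 without IP 2 or IP 3). Cxcl10 was higher by 1.24 ± 0.30 (adjusted p = 0.0243, and up to 0.0937 without IP 2, IP 3, IP 4, IV 2 or IV 4), and Cd274 by 1.39 ± 0.38 (adjusted p = 0.042, and up to 0.144 without any 1 of PBS 2, the IP libraries or the IV libraries). Trbv12-1 and Cd274 also lost their calls with no filter on low counts, and Ido1 on the deposited log2 CPM.

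Many changes against PBS were shared between the routes. Of 17123 genes, 2267 passed in the same direction in both comparisons, 1467 higher and 800 lower, against 333.1 and 137.5 for independent lists of these sizes, and 11 passed in opposite directions. The same-direction count was 884 without PBS 1, 1296 without IV 2, 1087 with only the 2 groups compared and 1137 with the acinar level as a covariate. Without IP 4, IV 1 and IV 2 it was 0 in edgeR, in which 0 genes then passed between IV and PBS (612 in limma voom, and 3691 at an unadjusted p under 0.05). Among genes called in both were Ifng, Gzmb, Cd274 and Cxcl10 (higher) and Insig1, a regulator of sterol synthesis, Elovl6 and Bub1 (lower). Both comparisons use the same PBS libraries. In 20 simulations all 9 libraries, PBS included, were drawn around the PBS means with each gene independent, and 0 genes passed the same way in both. Such draws lack shifts of whole gene groups between PBS libraries, whose interferon-gamma response medians were 3.41, 5.09 and 6.25 (log2 CPM). The simulated values therefore do not measure what such shifts add to the overlap. The simulated fold changes correlated across genes at a median r of 0.465 (0.444 to 0.496) and rho of 0.441, and 66% had the same sign. The observed r was 0.785, rho 0.71 and same-sign share 76.8%, and the covariance was 0.951 against a simulated 0.0871. The 3 PBS libraries cannot be split into parts of 2 or more, and part of the excess may come from the shared controls.

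**Figure D4:**
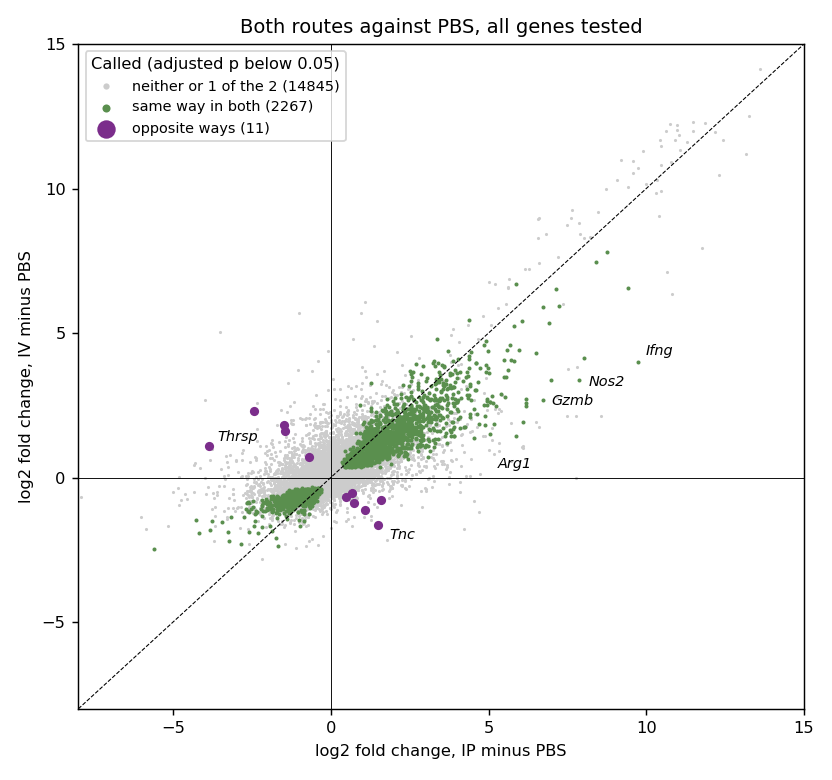
Log2 fold change of IV against PBS (vertical) plotted on that of IP against PBS (horizontal) for the 17123 tested genes, with the dashed line at equal change. The 2267 genes called the same way in both comparisons and the 11 called in opposite ways are coloured, and the remaining 14845 genes, acinar genes at the upper right among them, are grey.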

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

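The comparisons of tumour share, of Xist, of pigment genes and of the interferon and T cell levels of IV 4 were chosen after the values they bear on had been seen; the correlation concerning IV 4 and the splits were set beforehand.

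Some gene groups differed in the direct test between IP and IV and had medians of different direction against PBS. For lipogenesis this held for the median only, since in IV its mean was -0.0187 and camera pointed down, as in IP. The B cell list lay at a median log2 fold change of -2.26 in IP minus IV, the adipocyte list at -0.813, the lipogenesis list at -1.44, and the hypoxia and glycolysis list at 0.786; against PBS the medians were -0.33 and 2.03, -0.41 and 0.50, -1.78 and 0.02, and 0.43 and -0.21 in IP and IV. In each of them 1 route did not pass against PBS: IP for the B cell (camera adjusted p = 0.166) and adipocyte lists (0.196, and 0.0309 at the lowest, without PBS 2 or IP 4), IV for the lipogenesis (0.415, and 0.0315 without PBS 2) and hypoxia lists (0.145, and 0.0125 without IV 1). For the other route camera passed, but the adipocyte list in IV (0.0254) not without PBS 2 or IV 1 (up to 0.246), and with an estimated correlation none of these did (adjusted p = 0.292 for B cell and 0.611 for adipocyte markers in IV, 0.218 for lipogenesis and 0.45 for hypoxia in IP). With an estimated correlation none of the 4 passed between the routes either (adjusted p = 0.218, 0.334, 0.182 and 0.182). In addition 11 genes passed in opposite directions against PBS and also passed between the routes. Higher in IV and lower in IP were Igfbp5, Cr2, Thrsp, Fcer2a and Cygb, with IP minus IV changes of -3.06, -3.30, -4.95, -4.74 and -1.41. Higher in IP and lower in IV were Tnc, Ccn1, Inhbb, Tfrc, Fam129b and Sdc1, with changes of 3.14, 2.38, 2.19, 1.61, 1.2 and 1.16. With 1 library left out, 7 of the 11 lost a call against PBS: in IP Cr2 (adjusted p up to 0.143, without any 1 of the PBS or IP libraries), Cygb (0.0894, without PBS 3, IP 2 or IP 3) and Sdc1 (0.112, without PBS 1, PBS 3, IP 2, IP 3 or IP 4). In IV these were Igfbp5 (0.0545, without PBS 2), Inhbb (0.0553, without PBS 1), Cr2 (0.109, without PBS 1, PBS 2 or IV 2), Cygb (0.122, without PBS 1, PBS 2, IP 3 or IV 2) and Sdc1 (0.0666, without PBS 1 or IV 2). Fam129b (0.132, without any 1 of the PBS or IP libraries or IV 2) and Thrsp (0.138, without PBS 1, PBS 2, any 1 of the IP libraries, IV 1 or IV 2) lost theirs in IV too.

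Immune genes rose against PBS while pigment genes fell. A lower share of tumour tissue would raise genes of the host tissue together. The interferon-gamma response list in IP against PBS exceeded the 70 tested fibroblast, endothelial, mesothelial and adipocyte genes by 3.42 (medians 3.60 and 0.18, host quartiles -0.48 to 0.58). For that list this argues against a lower tumour share with these tissue cells in its place. A share lowered by incoming leukocytes stays open, since these 70 genes do not mark leukocytes. A lower tumour share alone would lower all pigment genes by 1 amount, but the changes of 10 of them ran from -0.17 to -1.81, with an SD 3.6 times their median standard error. A larger host share stays open for smaller rises: 1221 genes called higher in IP rose by no more than Xist (1.07 ± 0.31), and 1976 rose by more. The same limit applies to IV, in which Xist rose by 1.22 ± 0.31. There the list median was 1.25 for chemokine, 1.12 for dendritic cell and 0.80 for macrophage genes. It was 2.94 for interferon-gamma response, 2.31 for MHC class II and 2.03 for B cell genes. The labels do not say whether the tumour line expresses Xist. A response to the transferred cells, which the design names, remains a hypothesis for the larger rises.

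IV 4 lay nearer to PBS 3 (r = 0.982) than to IV 1 (0.948) or IV 2 (0.953). It also lay nearer to PBS 1 (0.9582), PBS 2 (0.9589), IP 2 (0.9575) and IP 3 (0.9598) than to these, but not to IP 4 (0.9454). IV 1 was about as near to IP 4 (0.9645) as to IV 2 (0.9643). A PBS library under an IV label is argued against by the interferon-gamma response median of IV 4, 8.80 against a highest PBS median of 6.25. The gap was 2.55, and IV 1 and IV 2 lay at 8.48 or more. Pancreatic tissue in IV 1 and IV 2 may account for part of the distance: outside pancreatic genes, the difference of IP 4 from IP 2 and IP 3 followed that of IV 1 and IV 2 from IV 4 across 17090 genes with r = 0.223 (rho 0.0416), which leaves this open. Fewer T cells in IV 4 are argued against: over the T cell list it lay above the mean of IV 1 and IV 2 by a median of 0.706 (quartiles 0.338 to 0.925), and level with IV 2 alone (0.00705, quartiles -0.406 to 0.203). Fewer transferred cells among them stays open, since these markers do not tell them from T cells of the mice. Trbv12-1, of the segment family of the OT-I receptor, had 113 counts in IV 4, 10 in IV 1 and 9 in the shallower IV 2. These counts do not point to fewer transferred cells in IV 4, but they are low and come from a single segment.

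For each comparison the 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05, and 1 split, the real one, gave as many genes. IP against PBS gave 5626 genes and at most 0 in any of the other splits in edgeR (489 at an unadjusted p under 0.05), and IP against IV gave 1780 and at most 2. IV against PBS gave 2753, and the split of PBS 1, PBS 3 and IV 4 against PBS 2, IV 1 and IV 2 gave 1999, which points to a structure among these samples other than the groups.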

How the results depend on the processing

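The settings on acinar transcripts, on IP 4, IV 1 and IV 2 and on depth were chosen after seeing the data. Across 21 settings, 170 of 403 called named gene results kept their direction and call (277 in the 17 settings fixed beforehand), and 53 of 66 calls of a list in 1 comparison did in the 15 settings run for lists other than the estimated correlation, which ended all 66. Calls of IP against PBS stayed within 1.5 times of 5626 (3956 to 6569 with 1 library left out). For IV against PBS (2753) there were 1210 with only the groups compared, 1260 with the acinar level as a covariate, 0 in edgeR without IP 4, IV 1 and IV 2 (3691 at an unadjusted p under 0.05, 612 in limma voom, with 1 IV library left), and 980 to 4580 with 1 library left out. For IP against IV (1780) there were 2759 in the DESeq2 Wald test, 1134 with the replicate block, 598 without those 3 libraries, and 673 to 2873 with 1 left out. Genes called the same way in both routes (2267) were 1087, 1137 and 0 in the first 3 of these settings, and 884 to 2996 with 1 left out. Without IP 4, IV 1 and IV 2, some results between IP and IV changed sign, with IV 4 the IV library left and acinar levels in IP 2 and IP 3 above it: Pnlip 8.82, Cpb1 6.36 and Tff2 8.86 (log2), and the acinar list (adjusted p = 9.08e-36); in IV against PBS, the acinar list (0.0105) and the erythroid list (0.658) did. Otherwise the cause was not tested. The replicate block gave 4502, 2044 and 1134 calls and 1702 the same way. It ended 3 calls of a list in 1 comparison and added 11. Among those ended was the interferon-gamma list between IP and IV (camera adjusted p = 0.523). Libraries with equal numbers deviated together by r = 0.05, 0.1, 0.0354, -0.0203, -0.137 and -0.399, so the numbers were not taken as pairs. Whether the numbers mark a shared cage or day is not known. Thinned to the depth of IV 2, 4737, 2323 and 1520 genes passed among 13949. No called result of a named gene changed sign under another scaling, and the signs of results called in neither fit were not compared. Low depth limits IV 2. Changes of 1.5-fold were mostly missed in simulations, in which 200 of 17123 genes changed. The adjustment was stricter there than in the real comparisons, whose sensitivity may differ.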

Other observations

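The comparisons of acinar levels with PBS and of Ifng with T cell markers and Trbv12-1 were chosen after the values had been seen; the further pancreatic genes were listed before their counts were examined.

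Immediate early and heat shock genes differed by route, as did the share of counts in mitochondrial genes, a sign of sample quality (1.71% to 1.9% in IP, 2.16% to 2.25% in IV and 2.27% to 3.09% in PBS). Of 16 immediate early and heat shock genes, 14 rose and 1 fell in IP against PBS (14 and 1 adjusted over the list alone; median 2.07; camera adjusted p = 4.51e-12, adjusted p = 0.182 with an estimated correlation), and 10 were higher and 0 lower in IP than in IV (14 and 1 adjusted over the list alone; median 1.31; camera adjusted p = 9.35e-16, adjusted p = 0.182 with an estimated correlation), with 1 lower without PBS 2. Jun, a subunit of the transcription factor AP-1, averaged 202 ± 22.4 CPM in IP, 62.9 ± 4.44 in IV and 28.3 ± 8.19 in PBS (SD, n = 3), and Atf3, a stress-induced transcription factor, 206 ± 36.4, 37.8 ± 6.28 and 13.9 ± 5.85. In IV against PBS 6 of the 16 rose and 0 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.00391, adjusted p = 0.446 with an estimated correlation; 4 without PBS 1, PBS 2, IV 2 or any 1 of the IP libraries), and 1 was called lower without PBS 3. Of 14 acute phase genes, 8 rose in IP against PBS (9 adjusted over the list alone; median 1.43; camera adjusted p = 0.0021, adjusted p = 0.444 with an estimated correlation), with Saa1, a serum amyloid gene, at 7.2 ± 2.35 and 0.965 ± 0.304 CPM (2.87 ± 0.51, adjusted p = 0.00158). Between IP and IV, 3 of the 14 were higher and 0 lower (5 and 0 adjusted over the list alone, median 0.83, camera adjusted p = 0.00342, adjusted p = 0.463 with an estimated correlation), with 5 higher without PBS 2, 6 without PBS 3 and 1 lower without IV 4. In IV against PBS 3 of the 14 rose and 0 fell (4 and 0 adjusted over the list alone), with 0 higher without PBS 1, PBS 2 or IV 2. The median was 0.84 there (camera adjusted p = 0.0921, as low as 0.00355 without PBS 3 or IV 2).

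Vessel and stromal lists gave mixed results. Flt1, a receptor of vascular growth factors, averaged 65.8 ± 4.03 CPM in IP, 18.5 ± 1.81 in IV and 12 ± 1.35 in PBS (IP minus PBS 2.45 ± 0.14, adjusted p = 9.55e-06), while the endothelial list had a camera adjusted p of 0.0635 in IP against PBS (as low as 0.028 without PBS 2, IP 2 or IV 2). The adhesion molecule list had a camera adjusted p of 0.174 in IP (0.0327 without PBS 3) and 0.00832 in IV against PBS (adjusted p = 0.292 with an estimated correlation), the fibroblast and matrix list 0.309 and 0.68, and the mesothelial list 0.426 and 0.291. Between IP and IV, the endothelial list was higher in IP (camera adjusted p = 0.0202, up to 0.139 without IP 3, IV 1 or IV 4), as was the fibroblast and matrix list (0.0408, up to 0.106 without PBS 1, IP 4, IV 1 or IV 2). The mesothelial list was lower in IP (0.0143, and 0.0637 without IP 2), and the adhesion molecule list did not pass (0.575). With an estimated correlation these had adjusted p = 0.557, 0.578 and 0.463 in the first 3. Among the largest falls in IP against PBS, Idi1, a gene of cholesterol synthesis, went from 13.3 ± 2.22 to 1.97 ± 0.164 CPM (-2.75 ± 0.34, adjusted p = 0.000173), and Insig1, a regulator of sterol synthesis, from 138 ± 33 to 23.7 ± 3.42 CPM (-2.54 ± 0.20, adjusted p = 2.45e-05).

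Acinar transcripts were abundant in IP 4, IV 1 and IV 2 and lay above PBS in IP 2 and IP 3 as well. A rise of acinar genes with the treatment stays open: 5 of the 6 treated libraries had acinar medians (log2 CPM) above the highest PBS library by over 1 (2.98, 3.26, 9.6, 10.3 and 7.79 in IP 2, IP 3, IP 4, IV 1 and IV 2, against -1.45), and IV 4 lay at -2.9. Pancreatic tissue in the dissected samples may be their source: of 16 further pancreatic genes in no list, 93.8% (15) were higher in IV 1 than in every PBS library by over 1 on the log2 scale, as were 14 in IP 4, 14 in IV 2, 11 in IP 3, 10 in IP 2 and 1 in IV 4. A rise of similar size in every mouse of a route is argued against by the acinar medians within each. They ran from 2.98 to 9.6 in IP and from -2.9 to 10.3 in IV. Otherwise the values do not tell a rise with the treatment from pancreatic tissue. Whether the treatment made such tissue harder to separate was not tested.

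A hypothesis is that the T cells reached by IP delivery held more Ifng transcript per cell than those after IV delivery, and not only that they were more numerous. If T cell number alone were behind it, the T cell list would be higher in IP than in IV by about as much as Ifng; the change of Ifng exceeded the median of the list by 5.58 (5.76 ± 0.61 against 0.17, quartiles -0.19 to 0.51), which argues against the number of all T cells alone. More transferred cells among them stays open: Trbv12-1, of the segment family of their receptor, was higher in IP by 2.45 ± 0.61 (adjusted p = 0.0288, up to 0.11 without IP 2, IP 3, IP 4 or IV 2), less than Ifng by 3.31 ± 0.86, but its lowest IV library (0.364 CPM) lay below the highest PBS library (0.384 CPM), so it does not measure these cells in each library. The ratio of Ifng to Cd8a CPM was 14.1, 13.9 and 10.8 in the IP libraries, 1.32, 0.652 and 0.392 in the IV libraries, and 0.0268, 0.117 and 0.097 in the PBS libraries. Host T and NK cells also express these genes, so the ratio may mix cell sources.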
